A study of Rattus norvegicus with 22 samples.

How the data were processed

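Liver RNA of 22 rats was sequenced in 4 groups, sham surgery or hepatic vagotomy with air or ozone exposure, with 5 to 6 rats in each group per the labels. Surgery was done at 12 weeks of age and was followed by 5 to 6 days of recovery, exposure to air or to ozone at 1 ppm for 4 hours on 1 or 2 days, and necropsy within 2 hours. RNA came from 10 to 20 mg of liver taken from a similar location, and libraries were made with the PrepX RNA-Seq kit. The labels give neither the strain nor the sex of the rats, nor which rats had 1 or 2 days of exposure, and exposure days were therefore not modelled. Replicate numbers count rats within a group and do not pair samples between groups.

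The deposited table holds a signal per gene and library, a normalised read count in which the read count of each gene was divided by 1 size factor per library. Per the submitters' processing notes, the tools were STAR with the rat build rn6, Partek, DESeq and DESeq2, without versions. All values of each of the 22 columns were whole multiples of 1 step within a tolerance of 0.001, which gave back the read counts, 14098863 to 21141337 per library. All 22 columns were used and 0 were left out. The 14971 genes are listed by symbol. Of these symbols 12462 match the rat annotation at hand and 616 match a synonym in it, but that annotation is of another build than rn6, so no coordinates are given. The lowest mean normalised count in the table was 1.04, and each gene had a read in at least 8 libraries.

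Normalised counts were analysed as log2(count + 1). Genes with a mean of at least 10 over all libraries were kept, 12424 genes or 83.0%. limma 3.58.1 in R 4.3.3 fitted the 4 group means in 1 model over all 22 libraries, with empirical Bayes moderation and an intensity trend. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. There were 6 comparisons, ozone against air in each surgery group, vagotomy against sham in each exposure, the difference between the ozone changes, and vagotomy against sham averaged over exposures. Agreement of the ozone changes was described by Pearson and Spearman correlations across genes and by a slope corrected for the noise of the estimates. Single measures per library were compared with exact permutation tests.

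There were 34 gene lists and 15 lists of cell type markers, of which 46 had at least 3 members tested. They were tested with camera of limma at its preset correlation of 0.01, with adjustment over the lists within a comparison, and again with an estimated correlation and with fry. Members past the threshold were counted over all genes tested and adjusted over the list alone. Several genes stand in more than 1 list.

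Genes were named by a rule. In each comparison with at least 20 called genes it took the 6 largest rises and the 6 largest falls among called genes with a mean normalised count of at least 50 and a gene name, and up to 4 members with the smallest p from each list that passed and from 9 lists set in any case. In comparisons with fewer calls it took each called gene up to 12, then the genes with the smallest p up to 6. The rule gave 204 genes, of which 96 are named in 128 combinations of gene and comparison. That part was chosen after the values were seen, as were the few genes outside the rule, which are marked where they stand. The comparisons, tests, lists, naming rule and alternatives were set before the data were examined, apart from the tests of explanations in the closing section, 5 of which were set only after the result they measure was seen, and 2 alternatives added afterwards, namely leaving out 4 libraries with 5.8S ribosomal RNA under 200 and using log2 5.8S ribosomal RNA as a covariate.

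The alternatives were pseudocounts of 0.5 and 5, no minimum count or a minimum mean of 50, rescaling to equal column totals or equal upper quartiles, quantile normalisation, the replicate number as a block, only the groups compared in the fit, the number after S in the sample description as a covariate, robust empirical Bayes, array weights, a fold minimum of 1.5, and leaving out each library in turn. The recovered read counts were tested with edgeR 4.0.16 (quasi-likelihood, with TMM factors or with the submitters' size factors) and DESeq2 1.42.0. Splits of the libraries into groups of the same sizes were drawn 100 times with a fixed seed.

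The procedure was tested on simulated data with the group sizes, depths and edgeR dispersions of these libraries and 200 changed genes, of which 198 were tested. limma found 44.6% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 97.0% of those changed 4-fold, and called 10 of 12226 unchanged genes. Libraries of 1 group were checked for copies. Over 50 pairs within groups the lowest chi-square per degree of freedom was 10.0, and log2 values correlated with r from 0.948 to 0.989. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.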

Results

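Liver gene expression was measured by RNA sequencing in 22 rats in a design with 2 factors, exposure and surgery. Rats had either sham surgery or a hepatic vagotomy, the severing of the vagus nerve branch that runs to the liver, and were then exposed to air or to ozone at 1 ppm for 4 hours a day. The labels give 1 or 2 days of exposure without saying which library had which. The groups held 5 sham air, 6 vagotomised air, 6 sham ozone and 5 vagotomised ozone libraries, each from a separate rat. The reads assigned to genes ranged from 16408931 to 18721031 per library in sham air, from 14098863 to 21141337 in vagotomised air, from 14737832 to 19469381 in sham ozone and from 16259568 to 17582912 in vagotomised ozone. Of 14971 genes listed by symbol, 12424 had a mean normalised count of at least 10 and were tested. The symbols carry no coordinates, so none are given for the genes named. Below, a change is a log2 fold change with its standard error (SE), and a gene is said to have risen or fallen when its adjusted p was under 0.05.

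Exposure separated the libraries along the first principal component, which held 29.9% of the variance. The 11 air libraries had scores from -42.0 to -12.8 and the 11 ozone libraries from 4.55 to 38.4. The component that came next, with 21.3% of the variance, set apart 4 libraries with low normalised counts of 5.8S ribosomal RNA. These were vagotomised air libraries 1 and 5, sham ozone library 3 and vagotomised ozone library 1. On the first component they also had the lowest scores of their exposure. These were -42.0 and -33.6 in air, against -27.9 or more in the other air libraries. In ozone they were 7.50 and 4.55, against 19.5 or more in the other ozone libraries. The 5.8S values of the 4 libraries ranged from 38.1 to 180 (normalised counts), against 342 or more in the other 18 libraries. Their summed counts over 63 small nucleolar RNAs, which guide the modification of ribosomal RNA, ranged from 111 to 179, against 1088 to 8771 elsewhere. No sham air library was among the 4, so each comparison below is also given without them, an alternative added after the data were seen.

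**Figure D1:**
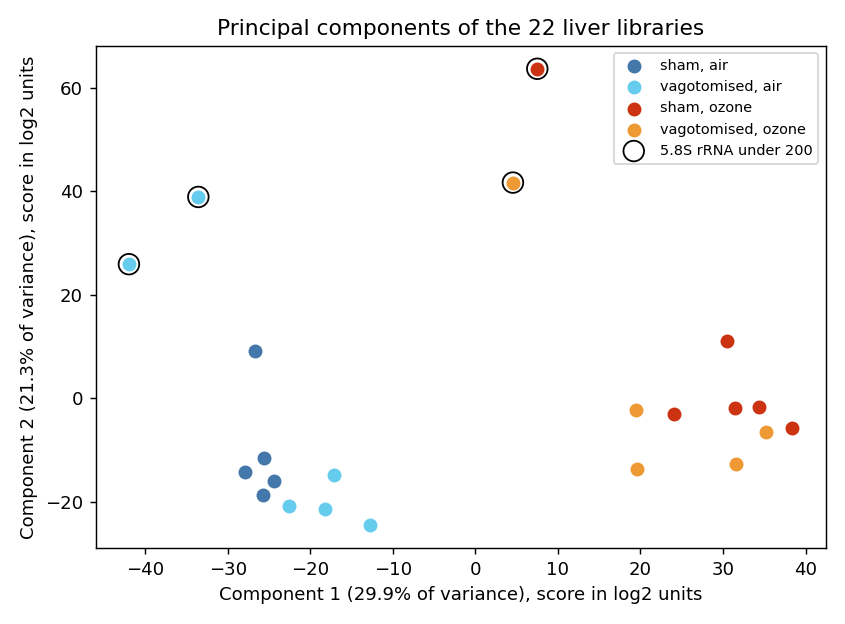
Scores of the 22 liver libraries on the first 2 principal components of log2 normalised counts (score in log2 units, share of variance on each axis). The 11 air libraries lie at negative scores of the first component and the 11 ozone libraries at positive ones, and the 4 circled libraries, with 5.8S ribosomal RNA under 200, lie apart on the other.

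The first comparison asked what ozone changed in the liver of rats with an intact hepatic vagus nerve, with n = 6 ozone and 5 air libraries. Some genes that degrade amino acids rose steeply. Sds, the serine dehydratase that feeds serine carbon into glucose production, rose by 4.58 ± 0.46 (adjusted p = 2.32e-07), and Got1, the cytosolic aspartate aminotransferase, by 2.79 ± 0.21 (adjusted p = 6.08e-09). Fkbp5, a co-chaperone gene switched on by glucocorticoids, went from a mean normalised count of 509 ± 252 to 2759 ± 412 (SD), a rise of 2.53 ± 0.31. Igtp, an interferon-induced GTPase, changed by -1.52 ± 0.19 (adjusted p = 3.25e-06).

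In this comparison limma called 3526 of 12424 genes (28.4%), of which 1809 rose and 1717 fell, and 708 of these changed at least 2-fold, 342 of them upward. At an unadjusted p under 0.05 there were 4845 genes, against 621 expected by chance. The largest rises among well expressed genes were those of Tpte2 (5.19 ± 0.39), Slc12a3, a sodium chloride cotransporter (4.72 ± 0.31), Car12, a carbonic anhydrase (4.70 ± 0.39), Sds, Fam69c (4.57 ± 0.37) and Spsb1 (4.35 ± 0.46). The largest falls were those of Ppp2r2b, a regulatory subunit of protein phosphatase 2A (-3.22 ± 0.33), Inhba, which encodes a subunit of activin (-2.95 ± 0.28), Osgin1 (-2.59 ± 0.40), Arrdc3 (-2.42 ± 0.55), Socs2 (-2.39 ± 0.82) and Hcn3, an ion channel (-2.32 ± 0.41). Socs2, a feedback inhibitor of growth hormone signalling, was called at adjusted p = 0.0317, but at 0.0855 without sham air library 2, 0.122 without sham air library 3 and 0.0626 without sham ozone library 6. Without the 4 libraries low in 5.8S the count was 4452. Rescaling the values to equal column totals shifted the median change of all genes by -0.102 and gave 33.9% of called genes as risen, against 51.3% as reported, and rescaling to equal upper quartiles gave 39.3%.

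**Figure D2:**
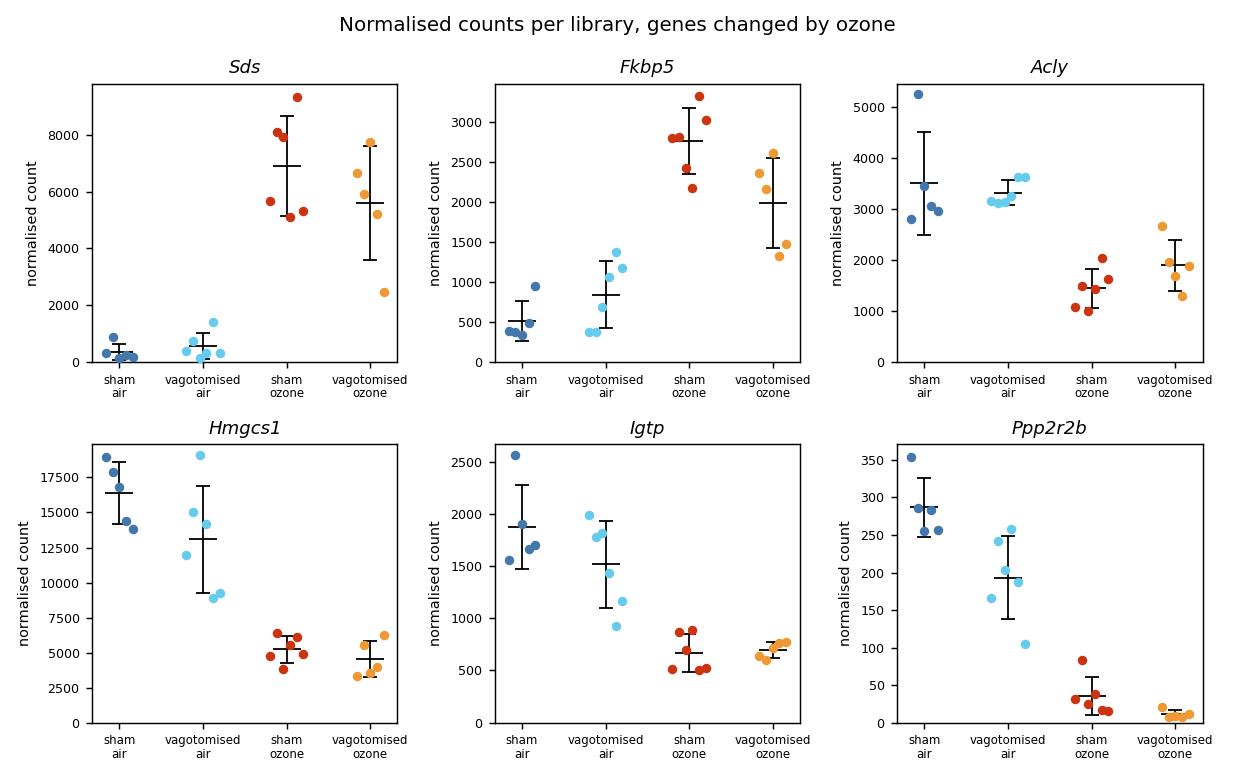
Normalised counts (linear axis from 0) of Sds, Fkbp5, Acly, Hmgcs1, Igtp and Ppp2r2b in the 4 groups, with 1 dot per library and the mean and SD of each group as a bar with whiskers. Sds and Fkbp5 were higher and the other genes lower after ozone, in sham and in vagotomised rats.

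Lists of amino acid and glucose genes passed by camera in sham rats, but none of them with an estimated correlation. Of 34 tested genes of the urea cycle and amino acid catabolism, 24 rose, 1 fell and 9 did not pass, and adjusted over the list alone 26 rose and 1 fell. This list passed the camera test at adjusted p = 2.57e-11, and had adjusted p = 0.241 with an estimated correlation. Its members include Slc25a15, the mitochondrial ornithine carrier (2.22 ± 0.16), Agxt, an alanine aminotransferase acting on glyoxylate (1.17 ± 0.12), Arg1, the arginase that releases urea (1.30 ± 0.18), and Tdo2, which opens the tryptophan ring (1.85 ± 0.22). Markers of periportal hepatocytes, the cells around the portal vein where urea is made, rose in 8 of 10 cases (8 adjusted over the list alone), with camera adjusted p = 0.000167 and adjusted p = 0.241 with an estimated correlation. Most of these markers (Hal, Sds, Gls2, Ass1, Arg1, Sdsl and Cps1) are also in the urea cycle and amino acid list. The gluconeogenesis list shares Sds, Tat, Got1 and Gpt with that list, so these lists are not separate results. Of 19 gluconeogenesis genes 8 rose and 11 did not pass (8 rose adjusted over the list alone), at camera adjusted p = 0.00172 and adjusted p = 0.253 with an estimated correlation. Ppargc1a, a coactivator of that programme, rose by 2.71 ± 0.32 (adjusted p = 1.59e-06). Of 20 glucocorticoid response genes 11 rose, 1 fell and 8 did not pass (11 rose and 2 fell adjusted over the list alone), at camera adjusted p = 0.00652 and adjusted p = 0.507 with an estimated correlation. Among 16 glycogen metabolism genes 1 rose, 9 fell and 6 did not pass (1 and 9 adjusted over the list alone), at camera adjusted p = 0.00645 and adjusted p = 0.207 with an estimated correlation. Stbd1, which tethers glycogen to membranes, changed by -1.97 ± 0.21.

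Some lipid synthesis genes fell in sham rats, and some genes of fatty acid oxidation rose. Of 19 fatty acid synthesis genes 9 fell and 10 did not pass (10 fell adjusted over the list alone), at camera adjusted p = 6.32e-05 and adjusted p = 0.253 with an estimated correlation. Acly, which makes cytosolic acetyl-CoA, changed by -1.28 ± 0.18, and Fads2, a fatty acid desaturase, by -1.08 ± 0.13. Of 25 cholesterol synthesis genes 2 rose, 11 fell and 12 did not pass (2 and 12 adjusted over the list alone), at camera adjusted p = 0.00119 and adjusted p = 0.573 with an estimated correlation. Hmgcs1, an early enzyme of the pathway, changed by -1.65 ± 0.19, and Nsdhl, a later one, by -0.78 ± 0.09. Among those that rose, and singled out after its value was seen and not recomputed under other settings, was Insig1, a brake on the pathway (1.49 ± 0.39). Of 24 targets of PPAR-alpha and genes of fatty acid oxidation 9 rose, 1 fell and 14 did not pass (9 and 1 adjusted over the list alone), at camera adjusted p = 0.0185 and adjusted p = 0.543 with an estimated correlation. Cpt1a and Cpt2, the carnitine palmitoyltransferases that bring fatty acids into mitochondria, rose by 0.97 ± 0.20 and 0.87 ± 0.13. Of 20 bile acid genes 4 fell, among them Baat, which conjugates bile acids (-1.14 ± 0.12), and 16 did not pass (4 fell adjusted over the list alone), and the list did not pass (camera adjusted p = 0.225).

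Interferon-stimulated genes were lower after ozone in sham rats, and genes for making ribosomes higher. Of 29 interferon-stimulated genes 20 fell and 9 did not pass (21 fell adjusted over the list alone), at camera adjusted p = 1.87e-09 and adjusted p = 0.253 with an estimated correlation. Besides Igtp they included Parp14 (-1.32 ± 0.13). Of 25 ribosome biogenesis genes 18 rose and 7 did not pass (20 rose adjusted over the list alone), at camera adjusted p = 4.61e-09 and adjusted p = 0.0582 with an estimated correlation, with the nucleolar genes Gnl3 at 1.31 ± 0.15 and Nolc1 at 0.81 ± 0.10. Among 20 antioxidant genes controlled by NRF2, 8 fell and 12 did not pass (10 fell adjusted over the list alone), at camera adjusted p = 0.00172 and adjusted p = 0.253 with an estimated correlation. They included Osgin1 and Nfe2l2, which encodes NRF2 itself (-1.22 ± 0.17). Of 27 acute phase genes, which the liver turns on in systemic inflammation, 3 rose and 2 fell, none of them adjusted over the list alone, and the list did not pass (camera adjusted p = 0.739). Of 21 immediate early genes 1 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.767). One of them, Atf3, changed by -2.17 ± 0.66 (adjusted p = 0.0162), but had adjusted p = 0.0557 without sham air library 2, 0.0505 without sham air library 4 and 0.0514 without sham air library 5.

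The remaining lists that passed in sham rats concerned energy, protein turnover, drug metabolism, the clock and hormone receptors. Of 39 oxidative phosphorylation genes 10 rose (3 adjusted over the list alone), at camera adjusted p = 0.00172 and adjusted p = 0.605 with an estimated correlation. Of 30 proteasome genes 7 rose (7 adjusted over the list alone), with Psmb4 at 0.74 ± 0.11, at camera adjusted p = 0.00259 and adjusted p = 0.507 with an estimated correlation. Of 22 autophagy and lysosome genes 6 rose and 1 fell (6 and 1 adjusted over the list alone), with the autophagosome gene Map1lc3b at 1.42 ± 0.14, at camera adjusted p = 0.0212 and adjusted p = 0.292 with an estimated correlation. Of 26 xenobiotic metabolism genes 8 rose (9 rose and 1 fell adjusted over the list alone), at camera adjusted p = 0.0295 and adjusted p = 0.573 with an estimated correlation. Por, the electron donor of cytochromes P450, rose by 2.54 ± 0.22, and Nr1i2, the pregnane X receptor, by 1.15 ± 0.13. Of 18 circadian clock genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with the clock repressor Cry2 at 1.11 ± 0.16 and Usp2 at 1.98 ± 0.39, at camera adjusted p = 0.0419 and adjusted p = 0.292 with an estimated correlation. Of 17 hormone and neurotransmitter receptor genes 6 fell (6 adjusted over the list alone), at camera adjusted p = 0.0449 and adjusted p = 0.507 with an estimated correlation. They included Nr3c1, the glucocorticoid receptor (-0.70 ± 0.15), and Thrb, a thyroid hormone receptor (-0.58 ± 0.12). When the 4 libraries low in 5.8S were left out, the autophagy list had camera adjusted p = 0.0655 and the receptor list 0.0918, and mitochondrially encoded transcripts passed upward at 0.0429, with adjusted p = 0.641 with an estimated correlation.

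**Figure D3:**
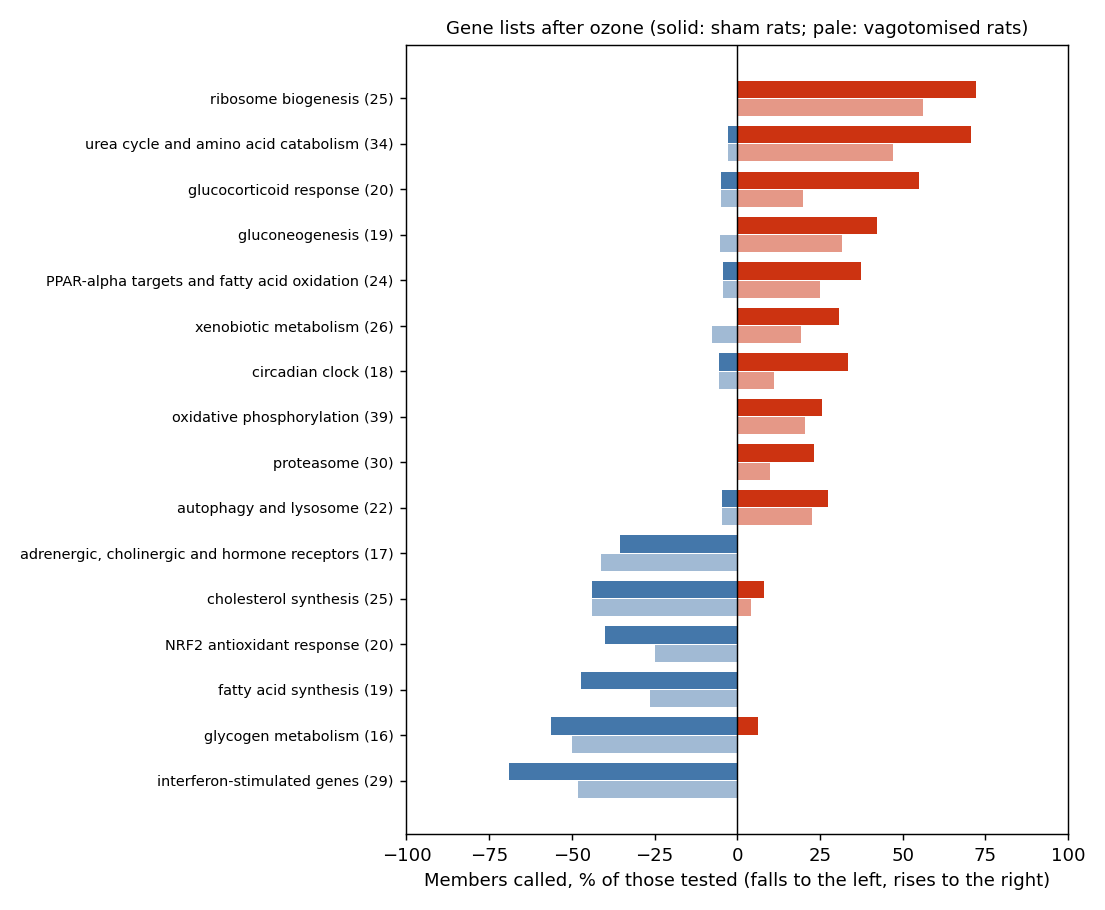
Share of the tested members of each gene list, in percent, that rose (to the right) or fell (to the left) after ozone, in sham rats (solid bars) and vagotomised rats (pale bars), for the 16 gene lists that passed the camera test in sham rats, cell type markers left out. Amino acid catabolism and ribosome biogenesis have the long bars to the right and interferon-stimulated genes the longest to the left.

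The next comparison asked what ozone changed in rats without a hepatic vagus nerve, with n = 5 ozone and 6 air libraries. The amino acid genes named for sham rats rose here as well, with Sds up by 3.65 ± 0.46 (adjusted p = 6.79e-06), Got1 by 2.63 ± 0.21, Slc25a15 by 1.99 ± 0.16, Arg1 by 1.37 ± 0.18, Tdo2 by 1.61 ± 0.22 and Agxt by 1.08 ± 0.12. Hmgcs1 changed by -1.52 ± 0.19 and Acly by -0.84 ± 0.18. Fkbp5 rose by 1.37 ± 0.31 and Ppargc1a by 1.48 ± 0.32. Cish and Socs2, both induced by growth hormone signalling, changed by -4.23 ± 0.84 (adjusted p = 0.000823) and -3.23 ± 0.82 (adjusted p = 0.00675).

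Here limma called 2619 of 12424 genes, of which 1422 rose and 1197 fell, and 201 and 207 of these changed at least 2-fold. At an unadjusted p under 0.05 there were 4021 genes, against 621 expected by chance. The largest rises were those of Tpte2 (4.44 ± 0.39), Slc12a3 (4.24 ± 0.31), Car12 (3.83 ± 0.39), Sds, Slc41a3, a magnesium transporter (3.35 ± 0.30), and Fam69c (3.03 ± 0.37). Beside Cish, large falls were those of Ppp2r2b (-4.04 ± 0.33), Socs2, Gdf15, a stress-induced hormone (-2.30 ± 0.69), and Osgin1 (-2.24 ± 0.40). Gdf15 had adjusted p = 0.0191, but 0.051 without vagotomised air library 1, 0.0624 without vagotomised ozone library 3 and 0.127 without the 4 libraries low in 5.8S. Without those 4 libraries the count was 2805.

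Metabolic lists that passed in vagotomised rats began with the urea cycle and amino acid catabolism, with 16 genes risen, 1 fallen and 17 not passing (18 and 2 adjusted over the list alone), at camera adjusted p = 4.63e-09 and adjusted p = 0.335 with an estimated correlation. Of 10 periportal markers, most of them also in that list, 6 rose and 1 fell (7 and 1 adjusted over the list alone), at camera adjusted p = 0.00395 and adjusted p = 0.335 with an estimated correlation. Of 19 gluconeogenesis genes 6 rose and 1 fell (6 and 1 adjusted over the list alone), at camera adjusted p = 0.00446 and adjusted p = 0.335 with an estimated correlation. Of 25 cholesterol synthesis genes 1 rose and 11 fell (1 and 14 adjusted over the list alone), at camera adjusted p = 3.81e-05 and adjusted p = 0.465 with an estimated correlation. Of 19 fatty acid synthesis genes 5 fell (1 rose and 6 fell adjusted over the list alone), at camera adjusted p = 0.00446 and adjusted p = 0.459 with an estimated correlation. Of 16 glycogen genes 8 fell (8 adjusted over the list alone), with Stbd1 at -1.15 ± 0.21 and Ugp2, which makes UDP-glucose, at -0.60 ± 0.10, at camera adjusted p = 0.00303 and adjusted p = 0.193 with an estimated correlation. Of 20 bile acid genes 5 fell (5 adjusted over the list alone), with Baat at -1.14 ± 0.12, at camera adjusted p = 0.0164 and adjusted p = 0.465 with an estimated correlation. Of 39 oxidative phosphorylation genes 8 rose (8 adjusted over the list alone), at camera adjusted p = 0.0237 and adjusted p = 0.926 with an estimated correlation. Cpt1a rose by 1.24 ± 0.20, while the PPAR-alpha list, with 6 genes risen and 1 fallen of 24 (7 and 1 adjusted over the list alone), had camera adjusted p = 0.0615. With the 4 libraries low in 5.8S left out, that list passed at 0.044 and the autophagy list at 0.0225, both upward, and they had adjusted p = 0.929 and 0.298 with an estimated correlation.

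Among immune and plasma protein genes of vagotomised rats, 14 of 29 interferon-stimulated genes fell (1 rose and 18 fell adjusted over the list alone), at camera adjusted p = 1e-06 and adjusted p = 0.389 with an estimated correlation. Parp14 changed by -1.29 ± 0.13 and Igtp by -1.07 ± 0.19. Of 26 complement and coagulation genes 8 fell (10 adjusted over the list alone), with the complement components C1s at -0.47 ± 0.11 and C6 at -0.41 ± 0.09, at camera adjusted p = 0.000352 and adjusted p = 0.335 with an estimated correlation. Of 27 acute phase genes 3 fell (3 adjusted over the list alone; camera adjusted p = 0.382), among them Fgb, a fibrinogen chain (-0.47 ± 0.10).

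Of the other lists in vagotomised rats, ribosome biogenesis had 14 of 25 genes risen (15 adjusted over the list alone), with Nolc1 at 0.79 ± 0.10, at camera adjusted p = 4.12e-05 and adjusted p = 0.268 with an estimated correlation. Of 20 NRF2 genes 5 fell (5 adjusted over the list alone), with Gclm, which takes part in glutathione synthesis, at -0.88 ± 0.13, at camera adjusted p = 0.00446 and adjusted p = 0.335 with an estimated correlation. Of 15 growth hormone genes 5 fell (5 adjusted over the list alone), including Stat5b, the transcription factor of that pathway (-0.60 ± 0.11), and Igfals, which stabilises circulating IGF1 (-0.74 ± 0.17), at camera adjusted p = 0.0082 and adjusted p = 0.335 with an estimated correlation. Of 17 receptor genes 7 fell (7 adjusted over the list alone), with Thrb at -0.78 ± 0.12 and the adrenergic receptor Adra1b at -0.99 ± 0.18, at camera adjusted p = 0.00937 and adjusted p = 0.335 with an estimated correlation. The glucocorticoid list had 4 genes risen and 1 fallen of 20 (4 and 1 adjusted over the list alone) and camera adjusted p = 0.727. Its median change, -0.01, was below 0, while its mean, 0.25, and the test lay above. Of 18 clock genes 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.756), with Cry2 at 0.93 ± 0.16. Of 21 immediate early genes 2 rose and 3 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.274), with the growth regulator Myc at -1.77 ± 0.37.

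Set side by side, the ozone changes of the surgery groups, which share no library, went the same way for most genes. Sham and vagotomised changes correlated across 12424 genes with Pearson r = 0.746 and Spearman rho = 0.686, and genes are not independent replicates. Of 1834 genes called in both groups, 1833 moved in the same direction. Of these, 1018 rose in both and 815 fell in both, against 207 and 165 expected if the calls were independent. Both comparisons use the same estimate of the spread for each gene, so their calls are not independent and these expected numbers may be too low. Of the 3526 genes called in sham rats, 3346 (94.9%) had the same sign in vagotomised rats. With the noise of each estimate taken out, the slope of the vagotomised on the sham change was 0.779 and the correlation 0.938.

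**Figure D4:**
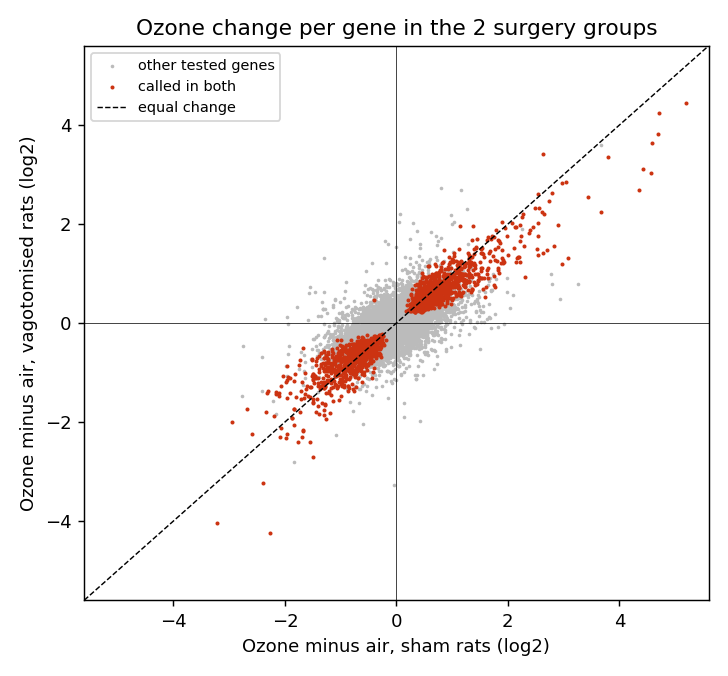
Log2 change after ozone in sham rats (horizontal axis) against that in vagotomised rats (vertical axis), 1 dot per tested gene, with genes called in both groups in red and equal change as a dashed line. Of the 1834 red genes, 1833 changed in the same direction in both groups.

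Whether vagotomy altered the ozone change was tested directly as the difference between the ozone changes, with positive values where it was higher in vagotomised rats. No single gene passed. The smallest p values were those of Lima1, which binds actin (1.17 ± 0.20, adjusted p = 0.105), Mavs, an adaptor of antiviral signalling (0.87 ± 0.17, adjusted p = 0.188), Zbtb47 (-1.43 ± 0.29, adjusted p = 0.196), Serinc4 (0.65 ± 0.13, adjusted p = 0.196), Slc22a23 (-0.86 ± 0.18, adjusted p = 0.25) and Tmcc2 (1.17 ± 0.26, adjusted p = 0.25). Beside the count of 0 by limma, 1147 genes had an unadjusted p under 0.05, against 621 expected by chance, edgeR called 0 genes, DESeq2 20, limma with array weights 13, and limma without the 4 libraries low in 5.8S 0. With array weights Lima1, Mavs, Zbtb47, Serinc4 and Tmcc2 each had adjusted p = 0.0404. Lima1 was called without sham air library 5 (adjusted p = 0.0375), without vagotomised air library 2 (adjusted p = 0.0473) and without sham ozone library 4 (adjusted p = 0.0455). Of 46 lists 16 passed by camera, 4 upward and 12 downward, and with an estimated correlation these 16 had adjusted p from 0.424 to 0.614. Glucocorticoid response genes had the smallest p beside 2 other lists, with a median difference of -0.59, no member passing (3 lower adjusted over the list alone), camera adjusted p = 0.000451 and adjusted p = 0.485 with an estimated correlation.

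A further comparison asked what vagotomy changed without ozone, with n = 6 vagotomised and 5 sham air libraries. No single gene passed, and the smallest adjusted p was 1. The genes with the smallest p were AABR07046778.1, a locus without a gene name (-2.82 ± 0.65), LOC100909481 (1.16 ± 0.28), Mss51 (1.11 ± 0.27), Tfpt (1.36 ± 0.34), Tmem115 (-0.40 ± 0.10) and Lyrm2 (-0.48 ± 0.13). Beside the count of 0 by limma, 387 genes had an unadjusted p under 0.05, against 621 expected by chance, edgeR and DESeq2 each called 0, and limma without the 4 libraries low in 5.8S 0. Recovery was simulated for ozone against air in sham rats, also 6 against 5 libraries, where limma found 74.6% of genes changed 2-fold and 44.6% of those changed 1.5-fold. No recovery was simulated for vagotomy in air. The simulated counts were drawn for each gene separately, without the difference across genes that the 4 libraries low in 5.8S share.

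Gene lists in air differed with vagotomy in 5 cases, without any member passing over all genes or adjusted over the list alone. Cell cycle genes had a median change of 0.49 over 24 members, at camera adjusted p = 2.14e-13 and adjusted p = 0.274 with an estimated correlation. Insulin and FOXO signalling genes had a median of 0.09 over 22 members, at camera adjusted p = 0.0261 and adjusted p = 0.891 with an estimated correlation. Cholesterol synthesis genes had a median of -0.13 over 25 members, at camera adjusted p = 0.00326 and adjusted p = 0.891 with an estimated correlation. Mitochondrially encoded transcripts had a median of -0.14 over 12 members, at camera adjusted p = 0.00875 and adjusted p = 0.891 with an estimated correlation. Interferon-stimulated genes had a median of -0.12 over 29 members, at camera adjusted p = 0.0197 and adjusted p = 0.891 with an estimated correlation. Without the 4 libraries low in 5.8S, of which 2 were vagotomised air libraries, the insulin list had camera adjusted p = 0.149 and the mitochondrial list 0.547. In that setting 3 further lists passed downward, cytosolic ribosome at camera adjusted p = 1.43e-10 (median -0.20), oxidative phosphorylation at 3.62e-06 and liver endothelial markers at 7.23e-05, each with adjusted p = 0.796 with an estimated correlation.

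In ozone, livers of vagotomised rats had more messenger RNA of cell division genes than those of sham rats, with n = 5 vagotomised and 6 sham libraries. Ccnb1, a mitotic cyclin, rose by 3.37 ± 0.52 (adjusted p = 0.00462), from a mean normalised count of 3.18 ± 3.86 to 32.0 ± 15.2 (SD). Its partner kinase Cdk1 rose by 3.34 ± 0.57 (adjusted p = 0.0075), Top2a, a topoisomerase of dividing cells, by 3.04 ± 0.50 (adjusted p = 0.00676) and Prc1, which organises the spindle, by 2.81 ± 0.53 (adjusted p = 0.0156). Slc2a5, a fructose transporter, rose by 1.30 ± 0.19 (adjusted p = 0.00352) and Tkfc, a fructose-metabolising kinase, by 0.98 ± 0.19. Ddit4 and Sesn2, both inhibitors of the growth kinase mTORC1, changed by -1.33 ± 0.27 (adjusted p = 0.0188) and -1.16 ± 0.29 (adjusted p = 0.0456).

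For this comparison limma called 166 genes, 100 higher and 66 lower in vagotomised rats, and 26 and 11 of these differed at least 2-fold. At an unadjusted p under 0.05 there were 1862 genes, against 621 expected by chance. Among well expressed genes the largest rises were those of Klhdc7a (1.33 ± 0.28), Slc2a5, Lima1 (1.06 ± 0.14), the transcription factor gene E2f2 (1.00 ± 0.22), Tkfc and Arhgef19 (0.97 ± 0.17). The largest falls were those of Ctdspl (-1.50 ± 0.31), Ppp2r2b (-1.43 ± 0.33), Ddit4, Pmepa1 (-1.24 ± 0.28), the stress-responsive kinase Plk3 (-1.18 ± 0.29) and Sesn2. The count fell to 20 without sham ozone library 1, 19 without sham ozone library 2, and 25, 60, 76 and 21 without vagotomised ozone libraries 2, 3, 4 and 5, and was 14 with these groups alone in the fit, 86 after quantile normalisation, 270 with array weights, 366.0 by DESeq2, 272 without the 4 libraries low in 5.8S and 322 with 5.8S as a covariate. Of the 20 called genes named for this comparison, 6 passed without each library in turn (Slc2a5, Lima1, Ccnb1, Top2a, Cdk1 and Arhgef19), of which Cdk1 (adjusted p = 0.0705) and Arhgef19 (adjusted p = 0.0639) were not called with these groups alone in the fit, and 14 did not, with 14 lost without sham ozone library 1, 14 without sham ozone library 2, and 11, 4, 9 and 13 without vagotomised ozone libraries 2, 3, 4 and 5. Sesn2 was not called with the replicate number as a block (adjusted p = 0.0532), by edgeR (adjusted p = 0.0525), after quantile normalisation (adjusted p = 0.0553) or with these groups alone in the fit (adjusted p = 0.19). Pmepa1 was not called with the block (adjusted p = 0.0532), and after quantile normalisation Plk3 (adjusted p = 0.0525), Cd14 (adjusted p = 0.0763), F11 (adjusted p = 0.0572) and Klkb1 (adjusted p = 0.0815) were not. With equal column totals Cd14 (adjusted p = 0.0589) and Klkb1 (adjusted p = 0.0755) were not called. The fit of these groups alone left 14 of the 20 uncalled, Ddit4 (adjusted p = 0.112) among them. Without the 4 libraries E2f2 had adjusted p = 0.0635. Rescaling to equal totals shifted the median change of all genes by 0.101 and gave 85.5% of called genes as higher in vagotomised rats, against 60.2% as reported, and quantile normalisation gave 73.3%.

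**Figure D5:**
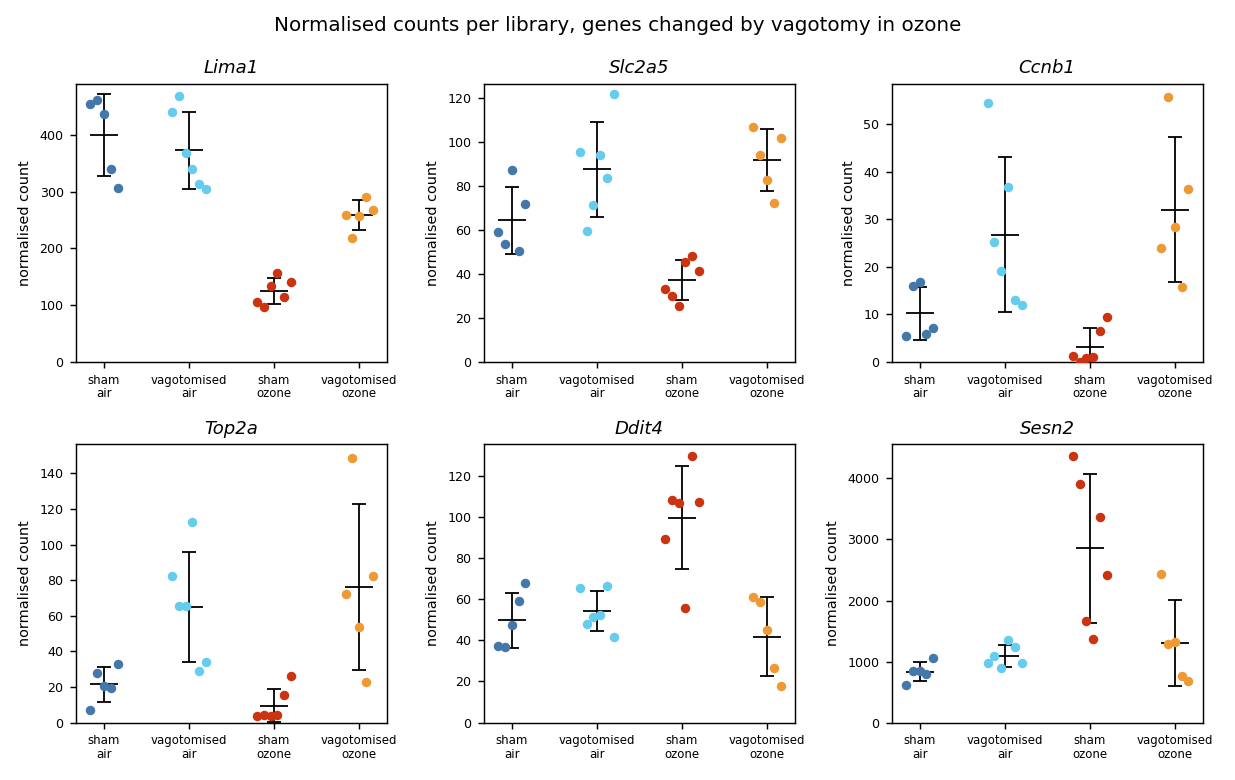
Normalised counts (linear axis from 0) of Lima1, Slc2a5, Ccnb1, Top2a, Ddit4 and Sesn2 in the 4 groups, with 1 dot per library and the mean and SD of each group as a bar with whiskers. In ozone, Lima1, Slc2a5, Ccnb1 and Top2a were higher and Ddit4 and Sesn2 lower in vagotomised than in sham rats.

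Lists passed in 18 cases in ozone, 3 upward and 15 downward in vagotomised rats, and with an estimated correlation these had adjusted p from 0.128 to 0.749. Of 24 cell cycle genes 8 rose and 16 did not pass (18 rose adjusted over the list alone), at camera adjusted p = 1.52e-16 and adjusted p = 0.128 with an estimated correlation. Of 26 complement and coagulation genes 2 fell (2 adjusted over the list alone), namely Klkb1, plasma prekallikrein (-0.44 ± 0.09), and F11, coagulation factor XI (-0.41 ± 0.09), at camera adjusted p = 1.48e-05 and adjusted p = 0.292 with an estimated correlation. Of 19 fatty acid synthesis genes 1 rose (3 adjusted over the list alone), namely Gpam, which starts triglyceride assembly (0.69 ± 0.15), at camera adjusted p = 0.0221 and adjusted p = 0.552 with an estimated correlation. Of 27 acute phase genes 1 fell (3 adjusted over the list alone), namely Cd14, a coreceptor for bacterial lipopolysaccharide (-0.53 ± 0.12), at camera adjusted p = 0.00925 and adjusted p = 0.438 with an estimated correlation. Of 21 lipoprotein genes 1 fell (2 adjusted over the list alone), at camera adjusted p = 0.0396 and adjusted p = 0.438 with an estimated correlation. Of 20 glucocorticoid response genes 1 fell (2 adjusted over the list alone), at camera adjusted p = 0.000929 and adjusted p = 0.438 with an estimated correlation. In that list Klf9 had a change of -0.58 ± 0.16 (adjusted p = 0.0697, but 0.0399 without the 4 libraries low in 5.8S, 0.0495 with 5.8S as a covariate and 0.046 with array weights) and Per1 of -0.79 ± 0.29 (adjusted p = 0.183). No member passed among 18 clock genes (0 adjusted over the list alone), with Cry1 at -0.71 ± 0.23 (adjusted p = 0.128, but 0.0333 with the replicate number as a block), at camera adjusted p = 0.00925 and adjusted p = 0.292 with an estimated correlation.

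Of the other lists in ozone, none of 25 cholesterol synthesis genes passed (3 fell adjusted over the list alone), with Insig1 at -1.28 ± 0.39 (adjusted p = 0.107) and Stard4 at -0.70 ± 0.21 (adjusted p = 0.0974), at camera adjusted p = 0.00998 and adjusted p = 0.629 with an estimated correlation. Insig1 passed without the 4 libraries low in 5.8S (adjusted p = 0.027), with array weights (adjusted p = 0.0336) and without vagotomised ozone library 1 (adjusted p = 0.0408). Stard4 passed without the 4 libraries (adjusted p = 0.0189), with array weights (adjusted p = 0.0178) and without sham ozone library 3 (adjusted p = 0.0328). Ppargc1a had a change of -0.95 ± 0.32 (adjusted p = 0.144). Cytosolic ribosomal protein genes had a median change of -0.23 over 46 members (0 adjusted over the list alone), at camera adjusted p = 9.36e-05 and adjusted p = 0.629 with an estimated correlation. Proteasome genes had a median of -0.13 over 30 members (0 adjusted over the list alone), at camera adjusted p = 0.000202 and adjusted p = 0.438 with an estimated correlation. Mitochondrially encoded transcripts had a median of -0.24 over 12 members (1 fell adjusted over the list alone), at camera adjusted p = 0.000556 and adjusted p = 0.438 with an estimated correlation. Markers of Kupffer cells, the macrophages of the liver, had a median of 0.22 over 11 members (0 adjusted over the list alone), at camera adjusted p = 0.0399 and adjusted p = 0.629 with an estimated correlation. The 6 remaining lists, all lower and without a member passing over all genes, were those of endoplasmic reticulum stress (camera adjusted p = 0.00925), insulin and FOXO signalling (camera adjusted p = 0.00945, 2 members adjusted over the list alone), ribosome biogenesis and oxidative phosphorylation (each camera adjusted p = 0.0221), bile acids (camera adjusted p = 0.0414, 1 member adjusted over the list alone) and growth hormone (camera adjusted p = 0.0457). They had adjusted p from 0.438 to 0.749 with an estimated correlation. Without the 4 libraries low in 5.8S the fatty acid synthesis list had camera adjusted p = 0.32, ribosome biogenesis 0.115 and bile acids 0.0924. In that setting antigen presentation class II (camera adjusted p = 0.019), NF-kB inflammatory genes (camera adjusted p = 0.0215) and interferon-stimulated genes (camera adjusted p = 0.0416) passed upward and periportal markers (camera adjusted p = 0.0392) downward, with adjusted p from 0.438 to 0.731 with an estimated correlation.

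Averaged over air and ozone, the vagotomy comparison asked which genes differed by surgery in the mean of both exposures, with 11 vagotomised and 11 sham libraries. A gene called here need not differ in each exposure, and in air alone no gene was called. Genes of mitosis were higher after vagotomy. Top2a rose by 2.29 ± 0.36 (adjusted p = 0.00708), Ccnb1 by 2.31 ± 0.37, Cdk1 by 2.25 ± 0.40, Ect2, which directs the splitting of dividing cells, by 2.22 ± 0.39, and the kinetochore and spindle genes Knl1 and Kif20a by 1.43 ± 0.25 and 1.13 ± 0.20. Of 24 cell cycle genes 4 rose (16 adjusted over the list alone), at camera adjusted p = 8.5e-27 and adjusted p = 0.0157 with an estimated correlation. The mean log2 level of the list was higher by 0.94 after vagotomy (exact permutation p = 4.69e-05, two-sided, labels exchanged within exposures).

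In this average limma called 14 genes, of which 13 rose and 1 fell, and 1150 had an unadjusted p under 0.05, against 621 expected by chance. The others among the 12 with the smallest p were Arhgap19 (1.52 ± 0.24), Slc2a5 (0.87 ± 0.14), Disp1, which releases hedgehog ligands (0.54 ± 0.09), Cfap70, a gene of cilia (0.65 ± 0.12), AABR07069282.1, a locus without a gene name (2.16 ± 0.38), and Mob3c (-0.51 ± 0.08), the 1 that fell. The mitotic genes had few reads, with mean normalised counts of Ccnb1 from 3.18 in sham ozone to 32.0 in vagotomised ozone and of Ect2 from 3.84 to 35.5. The count was 36 by edgeR, 114 by DESeq2, 42 with array weights, 37 without a minimum count, 3 at a minimum mean of 50, 4 with the replicate number as a block, 35 without vagotomised ozone library 4 and 25 without the 4 libraries low in 5.8S. With that block 8 of the 12 named genes were not called, with changes between 0.54 and 2.31, namely Ccnb1 (adjusted p = 0.0526), Cdk1, Ect2, Disp1 and AABR07069282.1 (each adjusted p = 0.0547), Knl1 (adjusted p = 0.0637), Kif20a (adjusted p = 0.0638) and Cfap70 (adjusted p = 0.0694). Cfap70 had adjusted p = 0.0517 without vagotomised ozone library 5, and Kif20a 0.0603 without the 4 libraries. The 7 other lists that passed were all lower after vagotomy and had adjusted p from 0.418 to 0.856 with an estimated correlation. They were mitochondrially encoded transcripts (camera adjusted p = 6.76e-06), complement and coagulation (camera adjusted p = 7.82e-06), cholesterol synthesis (camera adjusted p = 6.38e-05), proteasome (camera adjusted p = 0.00359), cytosolic ribosome (camera adjusted p = 0.00723), acute phase (camera adjusted p = 0.0101) and oxidative phosphorylation (camera adjusted p = 0.0223), with no member passing over all genes. Adjusted over the list alone, 3 mitochondrial, 2 complement and 1 cholesterol gene were lower, and none in the other 4 lists. Without the 4 libraries low in 5.8S, lists also passed downward for endoplasmic reticulum stress (camera adjusted p = 0.00658), glucocorticoid response (camera adjusted p = 0.00778), stellate cell markers (camera adjusted p = 0.0225), growth hormone (camera adjusted p = 0.0296), lipoprotein genes and negative acute phase proteins (each camera adjusted p = 0.0366), iron and heme (camera adjusted p = 0.0456) and the clock (camera adjusted p = 0.0457), and upward for Kupffer cell markers (camera adjusted p = 0.0225). These had adjusted p from 0.588 to 0.703 with an estimated correlation.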

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

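The tests of sequencing depth, of a loss of short RNAs alone, of the cell cycle list without the 4 libraries low in 5.8S ribosomal RNA and of other cell types were chosen only after the result was seen.

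Cell cycle genes were higher after vagotomy, by a mean log2 change of 0.94 (exact permutation p = 4.69e-05), with 0.63 in air (exact permutation p = 0.0173) and 1.25 in ozone (exact permutation p = 0.00433). The mean log2 level was 4.73 ± 0.21 in sham air, 5.37 ± 0.41 in vagotomised air, 4.26 ± 0.44 in sham ozone and 5.51 ± 0.45 in vagotomised ozone (SD). It was thus lower in ozone than in air in sham rats and higher in vagotomised rats. These ozone differences of the mean level were not tested. The exact test argues against a chance split of the libraries. The 4 libraries low in 5.8S do not account for it, since the mean change without them was 0.98. More cells of another type, each cycling as before, is argued against for the 9 cell types tested, in the average over exposures. This holds only so far as the markers stand for the cycling cells of those types, which was not tested. Of the 9 lists of markers 0 came within 2 standard errors of the cell cycle list, their mean changes lying between -0.11 and 0.18. The mesothelium list came closest, below the cell cycle list by 0.764 (SE of the difference 0.347). The neutrophil and nerve lists had 3 tested members each, and B and plasma cells, with 1 tested marker, were not tested. Kupffer cell markers, higher in vagotomised livers in ozone as given above, were not compared with the cell cycle list in ozone alone. More division, in hepatocytes or in any other cell type of the liver, stays open as a hypothesis. So does any effect of the vagotomy operation, other than the loss of the nerve, that sham surgery did not share. The design cannot separate such an effect from the loss of the nerve.

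Across genes the slope of the vagotomised on the sham ozone change was 0.779. It lies below the ratio of effect sizes, since the correlation with noise taken out was 0.938. Of 100 splits of the surgery labels within exposures, 9 gave a slope as low, the lowest other being 0.581 and the median 0.985. Chance is therefore not excluded, and a smaller ozone change was not shown. For a score of genes changed by ozone in both surgery groups the ozone change differed by -0.0734 (exact permutation p = 0.198). That score leaves out the 1692 genes called in sham rats only and the 785 called in vagotomised rats only, so it cannot decide whether the ozone change was smaller. The 4 libraries low in 5.8S are argued against as the source of the low slope, since the slope without them was 0.712. Whether vagotomised air livers were already shifted the ozone way cannot be told apart from no shift. The score was higher by 0.0454 in vagotomised air livers (exact permutation p = 0.132) and differed by -0.0280 in ozone (exact permutation p = 0.584), and neither passed. What difference this number of rats could show was not tested.

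Small RNAs set 4 libraries apart, vagotomised air 1 and 5, sham ozone 3 and vagotomised ozone 1. Sequencing depth is argued against, since 0 of the 4 had a read total outside the range of the other 18. A loss of short RNAs alone is argued against as well, since 906 other genes lay wholly above (438) or wholly below (468) in the 4 libraries, against 3.39 of 12393 expected by chance. Among the other 18 libraries the small nucleolar RNA sum was higher after ozone by 1.72 (exact permutation p = 0.000113) while 5.8S differed by 0.56 (exact permutation p = 0.224). Their ratio was higher by 1.15 (exact permutation p = 0.0034), so 5.8S did not rise as much. This argues against the small RNA content of the library as the source only so far as 5.8S stands for that content, which was not tested. The 4 libraries come from 3 groups, the labels give no batch, and neither a biological explanation nor RNA handling was tested, so both stay open.

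Lists whose ozone change differed with vagotomy by camera were these 16, with a lower ozone change in vagotomised rats for glucocorticoid response (adjusted p = 0.000451), insulin and FOXO signalling (adjusted p = 0.000451), cytosolic ribosome (adjusted p = 0.000451), ribosome biogenesis (adjusted p = 0.00157), proteasome (adjusted p = 0.00226), endoplasmic reticulum stress (adjusted p = 0.00368), complement and coagulation (adjusted p = 0.00424), lipoprotein and lipid droplet (adjusted p = 0.00942), ATF4 (adjusted p = 0.00942), circadian clock (adjusted p = 0.00942), urea cycle and amino acid catabolism (adjusted p = 0.0256) and xenobiotic metabolism (adjusted p = 0.0376). A higher one was found for cell cycle (adjusted p = 0.00157), interferon-stimulated genes (adjusted p = 0.00646), fatty acid synthesis (adjusted p = 0.0135) and antigen presentation class II (adjusted p = 0.02). With an estimated correlation all 16 had adjusted p from 0.424 to 0.614, and no member passed over all genes. Without the 4 libraries low in 5.8S the call was lost for cytosolic ribosome (adjusted p = 0.468), ATF4 (adjusted p = 0.206), urea cycle (adjusted p = 0.0836), lipoprotein (adjusted p = 0.079) and fatty acid synthesis (adjusted p = 0.0627). In that setting Kupffer cell markers (adjusted p = 0.000504), liver endothelial markers (adjusted p = 0.00565) and NF-kB inflammatory genes (adjusted p = 0.0184) also had a higher ozone change in vagotomised rats, and mitochondrially encoded transcripts (adjusted p = 0.0036) and bile acid genes (adjusted p = 0.0184) a lower one, with adjusted p from 0.51 to 0.554 with an estimated correlation.

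Single libraries stood apart from the rest of their group in 16 of 384 combinations of named gene and group (4.17%), and chance alone gives about 1 in 20. The measure is the gap to the nearest library over the range of the group, on the log2 scale. Vagotomised air library 1 was the lowest for Arg1 (0.654), Klf9 (0.665) and Tpte2 (0.773), and library 2 the highest for Nr3c1 (0.733). In sham air, library 3 was the lowest for AABR07069282.1 (0.819) and the highest for Kif20a (0.715), library 2 the highest for Stard4 (0.787) and library 1 the lowest for Thrb (0.838). In sham ozone, library 1 was the lowest for Car12 (0.727), library 2 the highest for C6 (0.695), library 3 the lowest for Ugp2 (0.700) and the highest for Zbtb47 (0.697), and library 6 the lowest for Socs2 (0.647). In vagotomised ozone, library 5 was the lowest for Got1 (0.758), library 4 the lowest for Klkb1 (0.823) and library 1 the highest for Myc (0.747). Library 1 of that group was also the lowest for 5.8S ribosomal RNA (0.783) and for the small nucleolar RNA sum (0.848), for which sham ozone library 3 was the lowest of its group (0.785).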

How the results depend on the processing

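The settings without the 4 libraries low in 5.8S ribosomal RNA and with 5.8S as a covariate were chosen only after the result was seen. Over the other settings the ozone counts in sham rats ranged from 1968 to 4689 and in vagotomised rats from 1356 to 3962, the count for vagotomy in air was 0 in each by limma, edgeR and DESeq2, and the correlation of the ozone changes ranged from 0.662 to 0.796. With a fold minimum of 1.5, which by construction removes small changes, 1968 genes were left in sham rats, 1356 in vagotomised rats and 102 for vagotomy in ozone. Array weights gave 3962 genes in vagotomised rats, 270 for vagotomy in ozone, 13 for the difference between ozone changes and 42 for vagotomy averaged. DESeq2 gave 366.0, 20 and 114 for the last 3 of these. For vagotomy in ozone quantile normalisation gave 86, a fit of these groups alone 14, leaving out the 4 libraries 272 and the 5.8S covariate 322. For vagotomy averaged no minimum count gave 37, a minimum mean of 50 gave 3 (it leaves 3 of the 12 named genes in the test), the replicate block 4, edgeR 36 with either scaling and leaving out the 4 libraries 25. Apart from the fold minimum and the minimum mean, the cause was not tested.

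Leaving out each library in turn gave 2972 to 3637 genes for ozone in sham rats, 1854 to 2826 in vagotomised rats, 0 to 0 for vagotomy in air, 19 to 217 for vagotomy in ozone, 0 to 1 for the difference between ozone changes, 11 to 35 for vagotomy averaged, and a correlation of 0.687 to 0.773. The lists called with an estimated correlation numbered 0 in each comparison except vagotomy averaged, with 1. Fry asks whether a list moves without comparing it with other genes. It called 24 lists for ozone in sham rats and 15 for ozone in vagotomised rats. For vagotomy fry called 0 in air, 4 in ozone and 1 averaged, and it called 0 for the difference. By camera at its preset correlation and a minimum mean of 50, the lists called numbered 8 for vagotomy in air. None of the 128 combinations of gene and comparison named by the rule changed direction in the settings run, and genes named outside the rule were not recomputed. Of the values under planned settings, 532 of 533 kept their side of the threshold for ozone in sham rats (Socs2 had adjusted p = 0.0506 with robust empirical Bayes), 481 of 481 for ozone in vagotomised rats, 75 of 75 for vagotomy in air, 306 of 334 for vagotomy in ozone, 66 of 71 for the difference and 127 of 135 for vagotomy averaged. When each library was left out, 214 of 286 did so for vagotomy in ozone. A fit with only the groups compared gives no value for the difference or the average, which use all 4 groups. The mitotic genes had low mean normalised counts, 42.4 for Top2a, 24.3 for Cdk1 and 17.8 for Ccnb1. Whether depth limits them was not tested.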

Other observations

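The test of the opposing vagotomy change against splits of the libraries was chosen only after the result was seen.

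Stress and growth arrest genes moved in both directions after ozone in sham rats, and their lists did not pass as groups. The genes named in this part were singled out after their values were seen, lie outside the naming rule and were not recomputed under other settings. Of 17 ATF4 targets, which respond to amino acid shortage and other stress, 7 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.085), with Psat1, an enzyme of serine synthesis, at 1.40 ± 0.20 (SE) and Slc3a2, a subunit of amino acid transporters, at 0.95 ± 0.11. Of 17 p53 and growth arrest genes 6 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.252), with the cell cycle inhibitor Cdkn1a at 2.15 ± 0.38 and the death receptor Fas at -1.49 ± 0.21. Of 19 heat shock genes 2 rose and 6 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.146), among the latter Hsph1 (-0.56 ± 0.15) and Hsp90ab1 (-0.49 ± 0.10). Of 17 hypoxia genes 4 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.454), with Higd1a at 1.05 ± 0.16 and P4ha1, a collagen hydroxylase, at -1.11 ± 0.17.

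Lipid droplet genes included a strong single change after ozone. Pnpla2, the lipase that opens triglyceride stores, rose by 2.14 ± 0.16 in sham rats and by 1.94 ± 0.16 in vagotomised rats, and Plin5, which coats lipid droplets, by 1.39 ± 0.21 and 1.40 ± 0.21, while the list as a whole did not pass (camera adjusted p = 0.0832 and 0.907). In vagotomised rats its median, -0.07, was below 0 and its mean, 0.06, above. Cell cycle genes in sham rats after ozone had 3 members risen and 9 fallen of 24 (3 and 12 adjusted over the list alone, camera adjusted p = 0.0844), and in vagotomised rats 2 risen and 0 fallen (1 and 0 adjusted over the list alone, camera adjusted p = 0.688). Markers of other liver cells did not pass after ozone in sham rats, with camera adjusted p = 0.351 for Kupffer cells, 0.23 for endothelial cells, 0.252 for stellate cells, 0.132 for neutrophils and monocytes and 0.444 for cholangiocytes.

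Other splits of the same libraries were compared with the real groups, 100 in each case with the real one among them. For ozone in sham rats 1 of 100 gave as many genes, the real one (3526 genes, highest other 2461). Likewise only the real one did for ozone in vagotomised rats (2619, highest other 1062), vagotomy in ozone (166, highest other 75) and vagotomy averaged (14, highest other 7). The same held for the correlation of the ozone changes (0.746, highest other 0.539). None of the other splits drawn came as high, but 100 splits cannot show a share below 1 in 100. The splits with 2461 and 1062 genes each put 5 libraries of the other exposure into each exposure group, so they come close to the real grouping reversed. For vagotomy in air 52 of 100 splits gave as many genes at an unadjusted p under 0.05 (387, highest other 2301), and for the difference between ozone changes 14 did (1147, highest other 2678), so chance is not excluded for either. The split with 2301 genes, several times the real count, put both vagotomised air libraries low in 5.8S into the sham air group. Whether the place of these libraries sets the counts of the splits in general was not tested. The split with 2678 genes did the same and put both ozone libraries low in 5.8S into the vagotomised ozone group.

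The vagotomy change in ozone ran against the ozone change in sham rats, with a correlation across genes of -0.392. Both comparisons use the shared sham ozone libraries. With these 6 libraries split into separate sets the correlation was below 0 in 20 of 20 splits (mean -0.189, from -0.307 to -0.0324). A negative correlation thus remained without shared libraries, but the 20 splits reuse the same 6 libraries and are not separate results. Of 100 splits of the surgery labels in ozone, 7 gave a mean as low, the lowest other being -0.293, so chance is not excluded and the opposition remains a hypothesis.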
